A study of Homo sapiens with 62 samples.

How the data were processed

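The 62 samples came from the human breast cancer lines MCF7 and T47D, grown without steroids for 48 h and then given vehicle, estradiol (E2, the natural estrogen), or ligands of other steroid receptors with or without E2, each at 10 nM. They comprised 18 T47D RNA libraries taken after 24 h, 10 MCF7 RNA samples taken after 24 h, and MCF7 chromatin immunoprecipitation sequencing (ChIP-seq) for the estrogen receptor (ER) with 22 peak lists and 12 input samples. The inputs came without processed files and were not analysed here. Raw reads were not used here, and all values rest on files the authors deposited.

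Per the submitters' processing notes, STAR, Cufflinks and DESeq2 were used for T47D RNA, and STAR, Cufflinks, TopHat and Cuffdiff for MCF7 RNA. The same notes name Bowtie2 and MACS for ChIP-seq and build hg19 throughout, without versions, settings or annotation. The T47D table deposited by the authors holds FPKM (fragments per kilobase of transcript, scaled to the fragments mapped in the library) for 20111 gene symbols, although its name speaks of read counts. Its values have decimals. Low values of each library were divided by those of the first vehicle library. Per library, 50.7 to 64.4% of these ratios, scaled for depth, lay near ratios of small whole numbers. Reads divided by length and depth give such ratios, but the share to be met without them was not computed. The MCF7 tables deposited by the authors give, per gene, a mean level, a log2 fold change (a log2 ratio) with its error, a test statistic, a p-value and an adjusted p-value. Neither the files nor the labels name the comparison group of these tables, and each MCF7 sample pools 2 replicates per the labels. The fold changes of the authors' deposited tables appear shrunk toward 0 to different degrees, so a difference in size between tables is not a test of a difference. Such differences entered only an added correlation with T47D. The authors' deposited peak lists give a score for each peak, in some lists with the fold enrichment and the −log10 p-value or q-value of the peak caller. Scores were used to rank peaks within a list and, as an alternative, to apply a stricter minimum score common to the lists compared.

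A count test had been planned for T47D. Because the file holds FPKM, log2(FPKM + 1) values were tested with limma 3.58.1 in R 4.3.3, with a mean for each of the 6 groups over all 18 libraries and with the trend and robust options of its empirical Bayes step. Genes with at least 1 FPKM in at least 3 libraries were tested, 12113 in all, and 7998 fell below this filter. FPKM carries no read depth. Depth relative to the first vehicle library, estimated from the steps between low values, ranged from 0.888 to 1.89, and 11555 to 11761 genes per library reached 1 FPKM. On the log2(FPKM + 1) scale the change of a gene with a low level is understated. Correlations of log2 values within groups ran from 0.992 to 0.996, and the highest between groups was 0.996. Labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between libraries.

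Comparisons were E2 against vehicle, each E2+ligand group against E2, and each pair of E2+ligand groups, 11 in all, with an F test of any difference between the 4 E2+ligand groups. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. The grouping, comparisons, tests, gene lists and the rule for named genes were written before the data were examined. For T47D the rule named the 10 largest changes per direction against E2 or vehicle, and the 5 largest per direction between ligands. Such genes had to pass the threshold, average at least 1 FPKM over the 18 libraries, and have all 3 libraries of a group above all 3 of the other. A level minimum planned for counts was read as 1 FPKM. In each MCF7 table the rule named the 5 largest changes per direction among genes past the threshold and in the top 50 percent by mean level. In each gene list the 4 members with the smallest p-values were named, as were ESR1, PGR, AR, NR3C1 and NR3C2, the last of which fell below the filter in T47D. Outside the rule, FKBP5, ZBTB16, SGK1, TSC22D3, MKI67, IFIT2, GDF15, DDIT3, CDKN1A, TFF1 and BIRC5 were singled out in further comparisons after their values had been seen.

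The 18 gene lists were classical estradiol-induced and estradiol-repressed genes, shared corticosteroid and NR3C receptor response genes, progestin-induced genes, androgen-induced genes, mineralocorticoid response and sodium transport genes, proliferation genes, cell cycle arrest genes, NF-kB and inflammatory genes and interferon-stimulated genes. The others were cholesterol and fatty acid synthesis genes, luminal identity genes, basal and mesenchymal genes, unfolded protein and integrated stress response genes, steroid receptors and coregulators, steroid metabolism genes, hypoxia genes, and markers of stromal, endothelial and blood cells. Each was tested with camera from limma at its preset correlation of 0.01 between genes and again with the correlation estimated from the libraries, adjusted over the 18 lists. Members changed were counted with p adjusted over all genes and with p adjusted over the list alone. Some lists share members, so their results are not separate evidence. FKBP5 was in the shared NR3C, progestin, androgen and mineralocorticoid lists, and SGK1 in all of these but the androgen list. HSD11B2 was in the progestin, mineralocorticoid and steroid metabolism lists, and BIRC3 in the shared NR3C and NF-kB lists. Genes higher or lower by a log2 fold of at least 1 in the authors' MCF7 E2 table were also tested as lists in T47D with camera at both correlations. So were genes higher by that fold in the authors' MCF7 dexamethasone table. Each MCF7 list was tested alone, and its p-values were not adjusted over lists or comparisons. The MCF7 dexamethasone list, and tests of the fixed lists between ligands, were added after seeing the data. The correlation and covariance that shared E2 libraries give between comparisons were simulated without ligand effects, while overlaps were set beside those of independent comparisons.

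Peaks were called shared when they overlapped by at least 1 bp, with 95% binomial intervals for shares, and 20 circular shifts of each list along its chromosomes gave the background share. Antibody lot F0515 gave 12 peak lists and lot L1911 10. Across lots, only E2 lists and a set of reference sites were compared. Each condition had 1 list except E2 and vehicle at 45 min with lot F0515. For 4 lists taken after 4 h, the title names another ligand than the treatment field. Titles E2+Dex, E2+DHT, E2+Aldo and E2+Prog stand beside the treatments progesterone, dexamethasone, DHT and aldosterone. File names follow the titles, and these lists were grouped by title. Genes near the peaks were not analysed here.

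The scripts were tested on simulated data. With 200 of 12113 genes changed, 50 at each fold, the simulated E2+DHT against E2 comparison recovered 46 at 1.5-fold, 49 at 2-fold, 50 at 3-fold and 49 at 4-fold, and 9 of 203 genes called had not been changed. The simulated E2+dexamethasone against E2+aldosterone comparison recovered 38, 48, 50 and 50 at these folds, and 12 of 198 genes called had not been changed. The peak overlap step returned the known answer in 6 of 6 checks with up to 3000 peaks.

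Alternatives covered the filter, a blocking term for replicate number, fits of the compared groups only, leaving out each library, an estimated correlation in list tests, thresholds of the MCF7 lists and tables, peak score and overlap. A pseudocount of 0.1, median-of-ratios scaling, quantile normalization, the difference of MCF7 tables, bins of peaks by score and the named sites were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the remaining steps.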

Results

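Gene expression and ER binding were measured in 2 ER-positive breast cancer lines given E2 together with ligands of NR3C receptors, the family that binds glucocorticoids, mineralocorticoids, progestins and androgens. T47D cells received vehicle, E2, or E2 with progesterone (Prog), the glucocorticoid dexamethasone (Dex), the androgen dihydrotestosterone (DHT) or the mineralocorticoid aldosterone (Aldo) for 24 h, with 3 RNA libraries in each of the 6 groups. Between 11555 and 11761 genes per library reached 1 FPKM, and 12113 genes were tested. MCF7 RNA was covered by 9 of the authors' deposited comparison tables, and ER binding in MCF7 by 22 peak lists. Among the 4 T47D groups given E2 with a ligand, 6714 genes differed. All T47D log2 changes and folds were computed after adding 1 FPKM, so for genes of low level they lie below the ratio of the means.

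E2 raised CXCL12, the chemokine that binds CXCR4, from 1.498 ± 0.338 to 48.96 ± 3.27 FPKM (mean ± SD, n = 3 per group, log2 change 4.33 ± 0.087 SE, adjusted p = 1.29e-15). TFF1, a trefoil peptide gene with a well-known ER binding site, rose by 2.34 ± 0.13 on the log2 scale, and SERPINA6, which encodes corticosteroid-binding globulin, by 2.47 ± 0.10. AQP3, a water and glycerol channel, fell from 39.6 ± 1.94 to 4.14 ± 0.336 FPKM (log2 -2.99 ± 0.079). RBP2, a retinol-binding protein, fell from 19.5 ± 4.01 to 1.32 ± 1.46 FPKM (log2 -3.30 ± 0.47, adjusted p = 6.36e-05). Among the receptors, PGR rose by 1.43 ± 0.10 (adjusted p = 1.43e-08), while NR3C1, the glucocorticoid receptor gene, fell by 0.61 (SE 0.097, adjusted p = 8.04e-05) and AR fell by 0.31 (adjusted p = 0.00362). ESR1 was at 22.5 FPKM with vehicle and 19.6 with E2 (adjusted p = 0.0941).

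With E2, 5486 genes changed against vehicle, 3606 higher and 1880 lower, of which 139 and 95 by at least 2-fold. All 28 tested classical estradiol-induced genes rose (28 adjusted over the list alone), among them CXCL12, OLFM1 (2.76 ± 0.080), KCNK5 (2.54 ± 0.082) and AREG (1.68 ± 0.066), and all 9 estradiol-repressed genes fell (9 adjusted over the list alone), among them CCNG2 and ERBB2. Both lists passed with adjusted p = 0.00379 with an estimated correlation. Of 30 proliferation genes, 26 rose (26 adjusted over the list alone), led by the replication licensing genes MCM6 (0.74 ± 0.064) and MCM7 (0.60 ± 0.066), with list adjusted p = 2.22e-06 at the preset correlation and adjusted p = 0.395 with an estimated correlation. Of 19 shared corticosteroid and NR3C response genes, 10 fell (10 adjusted over the list alone), among them FKBP5 (-1.03 ± 0.076) and TSC22D3 (-0.81 ± 0.071), and BIRC3 rose, with adjusted p = 0.121 with an estimated correlation. Of 15 mineralocorticoid response and sodium transport genes, 10 fell (10 adjusted over the list alone), led by ATP1B1 (-0.86 ± 0.059), and of 15 androgen-induced genes 8 fell and 2 rose (9 and 2 adjusted over the list alone), led by NDRG1. Both had adjusted p = 0.0771 with an estimated correlation.

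Of 12 cell cycle arrest genes 6 fell with E2 (7 fell and 1 rose adjusted over the list alone), among them BTG1 and CDKN2B, with adjusted p = 0.215 with an estimated correlation. Of 13 NF-kB and inflammatory genes 7 rose (7 adjusted over the list alone), led by CCL2 (1.21 ± 0.10), with adjusted p = 0.593 with an estimated correlation. Of 14 luminal identity genes 7 fell and 2 rose (7 and 3 adjusted over the list alone), with ELF3 at -1.17 ± 0.067 and adjusted p = 0.395 with an estimated correlation. Of 16 interferon-stimulated genes 4 fell (4 adjusted over the list alone), led by OAS2, with adjusted p = 0.647 with an estimated correlation. The progestin-induced (4 of 16 higher, 5 lower), cholesterol and fatty acid synthesis (1 of 19 higher, 4 lower), unfolded protein and integrated stress response (5 of 15 higher, 4 lower) and steroid metabolism lists (4 of 13 higher, 4 lower) moved in neither direction (adjusted p = 0.215, 0.159, 0.676 and 0.934), with the same numbers adjusted over the list alone. Hypoxia genes (6 of 11 higher, led by ADM, and 3 lower, led by NDRG1), steroid receptors and coregulators (2 of 10 higher, 3 lower) and basal and mesenchymal genes (1 of 8 higher, CD44, and 1 lower, CDH3) did not move as lists either (adjusted p = 0.934, 0.252 and 0.951). Adjusted over the list alone, only CDH3 of these was lost. Median, mean and test differed in sign for the basal, stress, receptor, steroid metabolism and hypoxia lists. Of the markers of stromal, endothelial and blood cells only 3 were expressed enough to be tested, and CD68 was lower (-0.33 ± 0.13), a call not kept when adjusted over the list alone. The mitochondrially encoded genes and the ribosomal protein genes also shifted in share of FPKM, from 14.6 ± 1.22% to 10.8 ± 0.968% and from 12.7 ± 1.33% to 16.3 ± 1.74% (mean ± SD, vehicle to E2). The share of changed genes that were higher was 65.7%, but 52.5% with median-of-ratios scaling and 50.9% with quantile normalization, so the excess of higher genes depended on scaling.

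**Figure D1:**
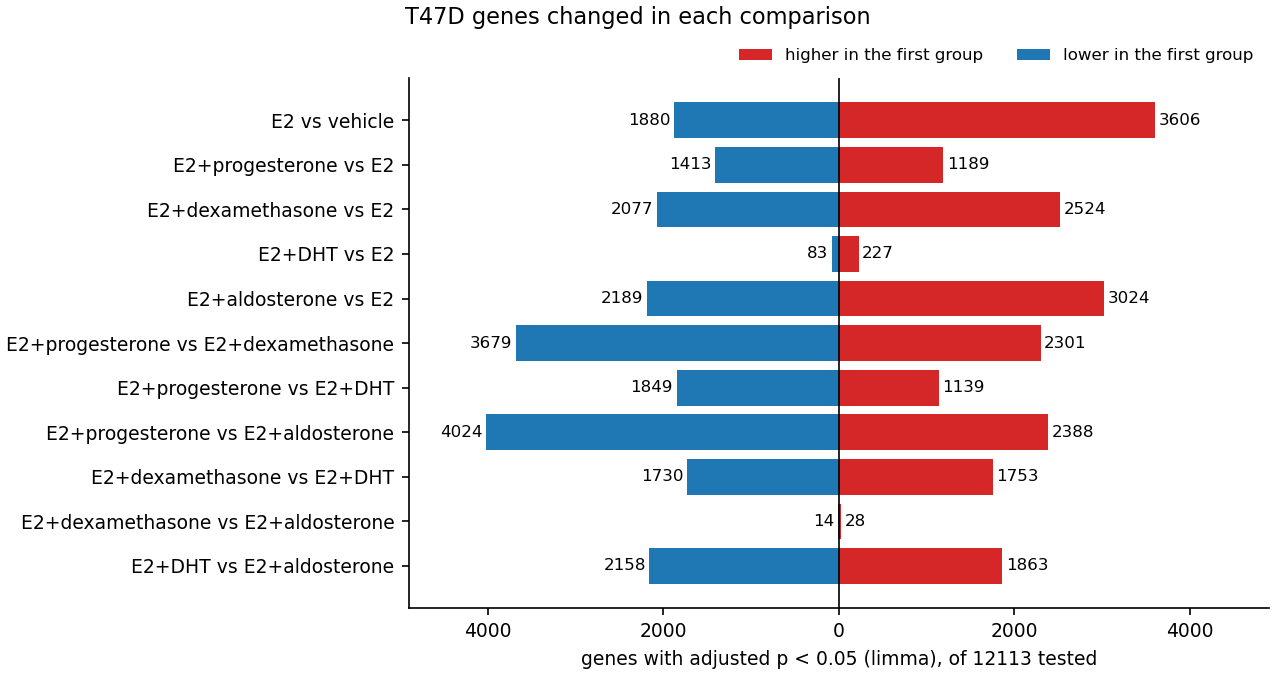
Genes changed in T47D in each of the 11 comparisons. Bars show the number of genes past the adjusted p threshold, to the right of 0 for genes higher in the group named first and to the left for genes lower in it, out of 12113 tested with 3 libraries per group. Aldosterone added to E2 changed 5213 genes and DHT 310, while the dexamethasone and aldosterone groups differed in 42.

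**Figure D2:**
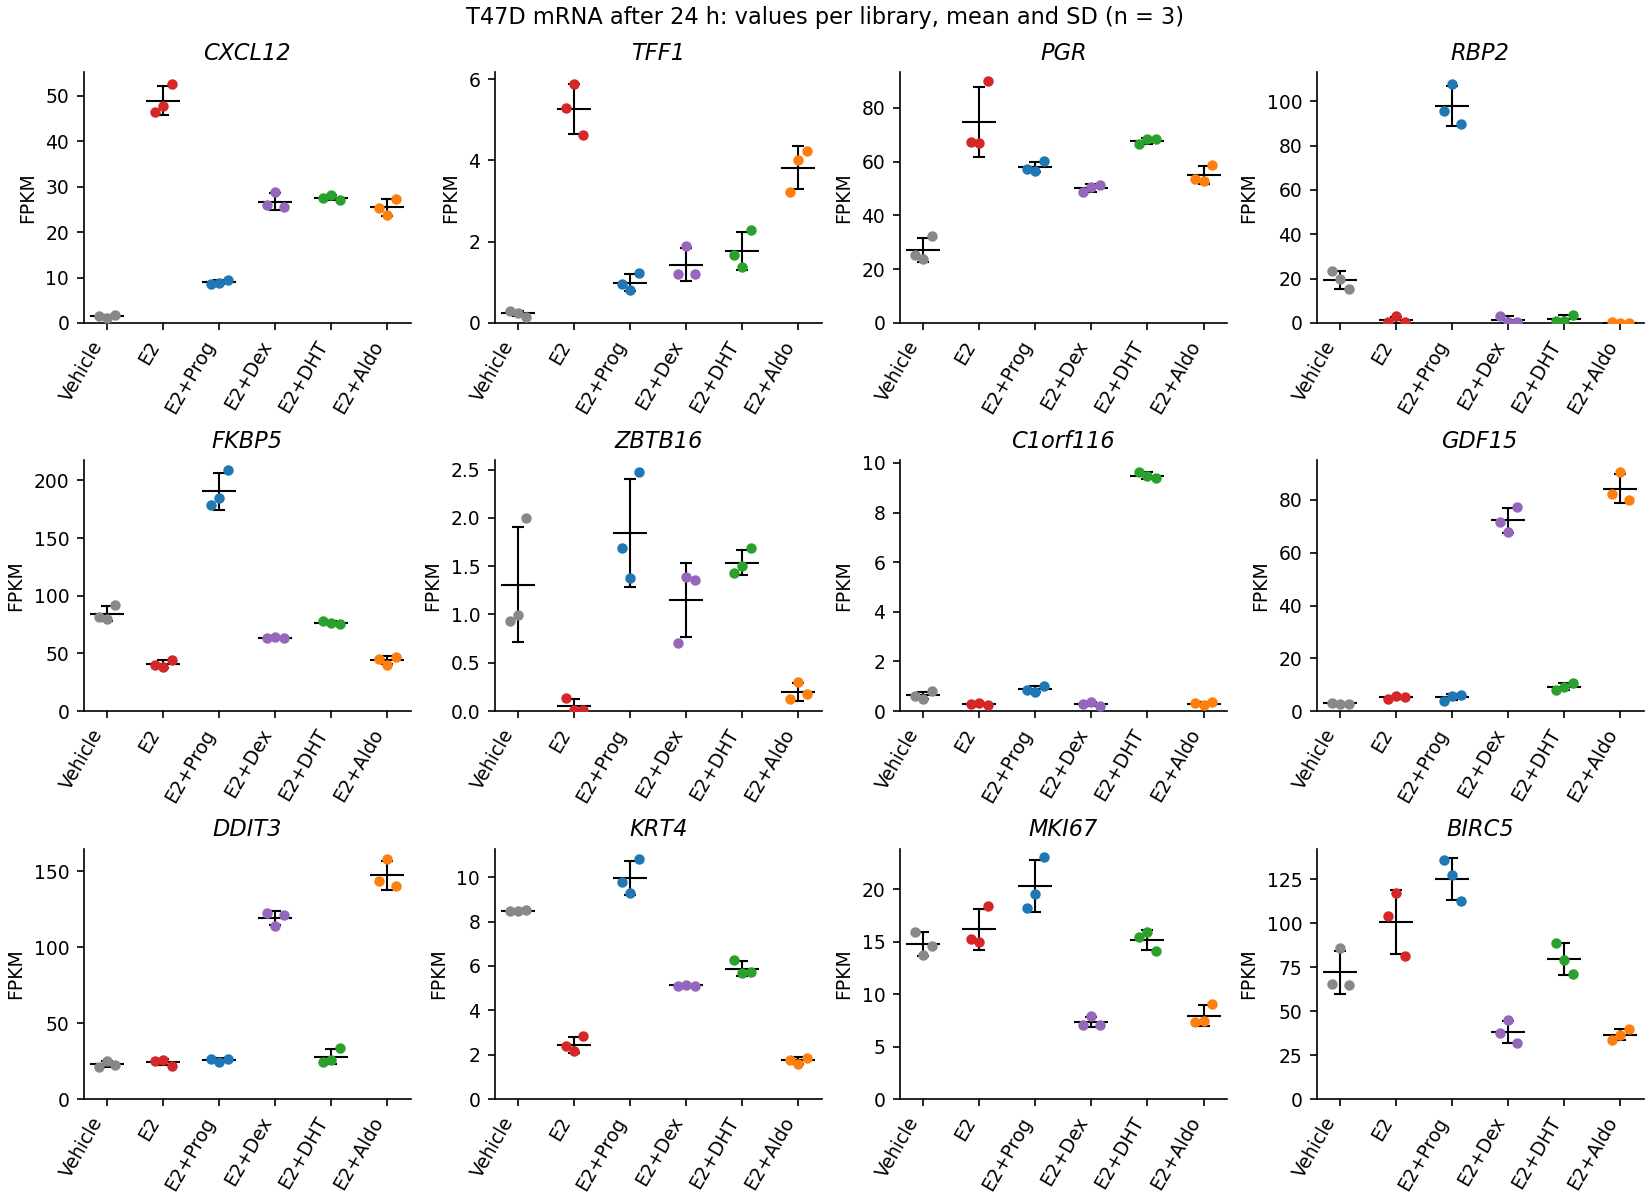
Levels of 12 genes in T47D, picked from named genes and list members after their values had been seen. Points are single libraries in FPKM, and bars show the mean and SD of 3 libraries per group. CXCL12 rose with E2 and was lower with every added ligand, RBP2 was highest with progesterone, C1orf116 rose with DHT, and GDF15 and DDIT3 rose with dexamethasone and aldosterone.

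Progesterone added to E2 raised RBP2 to 97.7 ± 9.10 FPKM (log2 change from E2 5.58 ± 0.47, adjusted p = 7.45e-07) and S100P, a calcium-binding protein gene, by 4.43 ± 0.16. AQP3 rose by 3.03 ± 0.079 to 41.0 ± 0.112 FPKM, and NDRG1 by 2.61 ± 0.11, both genes that E2 had lowered. HSD11B2, whose product inactivates cortisol, rose by 2.53 ± 0.095. CXCL12 fell to 8.95 ± 0.437 FPKM (log2 -2.33 ± 0.087, adjusted p = 2.58e-12), TFF1 fell by 1.65 (SE 0.13) and the chemokine gene CCL2 fell by 1.58 (SE 0.10). AR fell by 0.58 (SE 0.077, adjusted p = 2.42e-05) and PGR fell by 0.35 (adjusted p = 0.0233), and ESR1 was at -0.01.

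Against E2, 2602 genes changed with added progesterone, 1189 higher and 1413 lower, of which 123 and 42 by at least 2-fold. The share higher was 45.7%, and 48.4% with quantile normalization, but 56.6% with median-of-ratios scaling. The direction of this majority thus flipped with the latter scaling but not the former. It also flipped when 1 library was left out, to 51.4% without E2 replicate 3 and 50.4% without E2+Progesterone replicate 1. Of 15 mineralocorticoid response and sodium transport genes 12 rose (12 adjusted over the list alone), including the sodium pump subunits ATP1A1 (2.30 ± 0.070) and ATP1B1 (1.58 ± 0.059), and of 19 shared NR3C response genes 14 rose and 1 fell (16 and 1 adjusted over the list alone), including MT2A, FKBP5 (2.19) and SGK1 (2.24 ± 0.083). Both lists passed with adjusted p = 0.00474 with an estimated correlation, and they share members such as FKBP5 and SGK1. Of 16 progestin-induced genes 12 rose (13 adjusted over the list alone), including KRT5 (1.89 ± 0.13) and FASN (1.29 ± 0.096), with adjusted p = 0.0155 with an estimated correlation, and of 13 steroid metabolism genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), led by HSD11B2, SRD5A1 and AKR1C3, with adjusted p = 0.0115 with an estimated correlation. Reads of AKR1C genes may be shared between paralogs, as may those of metallothionein genes such as MT2A.

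Of 28 estradiol-induced genes, 15 fell and 3 rose with progesterone (16 and 4 adjusted over the list alone), with adjusted p = 0.207 with an estimated correlation. Of 30 proliferation genes 15 rose and 5 fell (15 and 5 adjusted over the list alone). PLK1 and MYBL2, which act late in the cycle or in its transcription program, rose by 0.61 and 0.57, while MCM6 fell by 0.44, and the list had adjusted p = 0.501 with an estimated correlation. Androgen-induced genes (7 of 15 higher, 3 lower, and 7 and 4 adjusted over the list alone) had adjusted p = 0.0802 with an estimated correlation. Cell cycle arrest genes (5 of 12 higher, 2 lower, and 5 and 3 adjusted over the list alone) included CDKN1A at 0.92 and had adjusted p = 0.378 with an estimated correlation. Interferon-stimulated genes (6 of 16 lower, 8 adjusted over the list alone) also had adjusted p = 0.378 with an estimated correlation. Cholesterol (6 of 19 higher, 2 lower), stress response (4 of 15 higher) and hypoxia genes (3 of 11 higher, 1 lower) passed at the preset correlation only, with adjusted p = 0.441, 0.248 and 0.207 with an estimated correlation, and with 6, 5 and 4 higher adjusted over the list alone. Estradiol-repressed, NF-kB, luminal, basal, receptor and stromal lists did not pass (adjusted p = 0.614, 0.289, 0.105, 0.253, 0.239 and 0.494).

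Dexamethasone added to E2 raised GDF15, a stress-induced cytokine of the TGF-beta superfamily, from 5.18 ± 0.619 to 72.2 ± 4.80 FPKM (log2 3.57 ± 0.12, adjusted p = 6.89e-12) and DDIT3, which encodes the stress transcription factor CHOP, from 24.4 ± 2.11 to 119.2 ± 4.66 FPKM (log2 2.25 ± 0.099). The lysosomal gene LAMP3 rose by 2.99 ± 0.19, LCN2 by 2.31 ± 0.12, and the reductase genes AKR1C2 and AKR1C1 by 3.22 ± 0.11 and 2.98 ± 0.13, with reads that paralogs may share. BIRC5, which encodes survivin, fell by 1.38 (SE 0.14), INSIG1, a sterol-regulated gene, fell by 1.41 (SE 0.11) and TFF1 fell by 1.37 (SE 0.13). FKBP5 rose by 0.63 (adjusted p = 5.54e-06), ESR1 fell by 0.34 (SE 0.088, adjusted p = 0.00532) and PGR fell by 0.55 (adjusted p = 0.000487), while NR3C1 rose by 0.39 (adjusted p = 0.00412).

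Against E2, 4601 genes changed with dexamethasone, 2524 higher and 2077 lower, of which 126 and 94 by at least 2-fold. The share higher was 54.9%, and 51.3% with quantile normalization, but 46.9% with median-of-ratios scaling, so the direction of this majority flipped with that scaling only. All 30 proliferation genes fell (30 adjusted over the list alone), among them CCNA2 (-1.20 ± 0.082), AURKA (-1.02 ± 0.070) and PLK1 (-1.09 ± 0.079), a median log2 change of -0.99, with adjusted p = 0.0407 with an estimated correlation. Of 15 unfolded protein and integrated stress response genes 10 rose (10 rose and 1 fell adjusted over the list alone), among them TRIB3 (1.71 ± 0.076), DDIT3, CHAC1 (2.11 ± 0.10) and the chaperone gene HSPA5 (1.18 ± 0.058). That list, the shared NR3C response list (14 of 19 higher, 14 adjusted over the list alone, led by MT1X, DUSP1, BIRC3 and KLF9) and the steroid metabolism list (8 of 13 higher and 2 lower, 8 and 4 adjusted over the list alone) each had adjusted p = 0.0407 with an estimated correlation. Of 19 cholesterol and fatty acid synthesis genes 13 fell (14 adjusted over the list alone), among them SCD (-1.10 ± 0.073), IDI1 (-0.92 ± 0.084) and LDLR (-1.20 ± 0.11), with adjusted p = 0.048 with an estimated correlation. Of 13 NF-kB and inflammatory genes 11 rose and 1 fell (12 and 1 adjusted over the list alone). They included TNFAIP3 (1.64 ± 0.12), an inhibitor of NF-kB signalling that NF-kB induces, and IRF1 (1.20 ± 0.096), and the list had adjusted p = 0.0786 with an estimated correlation.

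Estradiol-induced genes fell more often than they rose with dexamethasone (16 of 28 lower and 2 higher, 17 and 3 adjusted over the list alone), with AREG among the higher ones, and estradiol-repressed genes were higher in 5 of 9 and lower in 1. The 2 lists and the basal list (5 of 8 higher, led by KRT6B at 1.45 ± 0.090) each had adjusted p = 0.226 with an estimated correlation. Cell cycle arrest genes (6 of 12 higher, 1 lower) included CDKN1A (1.48 ± 0.080) and GADD45A (1.55 ± 0.096) and had adjusted p = 0.204 with an estimated correlation. Mineralocorticoid (9 of 15 higher, 1 lower), androgen-induced (7 of 15 higher, 1 lower) and interferon-stimulated genes (7 of 16 lower) had adjusted p = 0.233, 0.306 and 0.43 with an estimated correlation. The numbers for these lists were the same adjusted over the list alone. Progestin-induced, luminal, receptor, hypoxia and stromal lists did not pass (adjusted p = 0.124, 0.162, 0.779, 0.58 and 0.783), and for the stromal markers, of which CD68 was higher by 0.54, the median was below 0 and the test pointed up.

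Aldosterone added to E2 raised GDF15 to 84.3 ± 5.57 FPKM (log2 3.79 ± 0.12, adjusted p = 2.27e-12), DDIT3 to 147.3 ± 9.55 FPKM (log2 2.55 ± 0.099), AKR1C2 by 3.45 ± 0.11 and LCN2 by 2.56 ± 0.12. OLFML3 fell by 1.79 (SE 0.10), DEPDC1B fell by 1.56 (SE 0.11), the desaturase gene FADS2 fell by 1.45 (SE 0.094) and BIRC5 fell by 1.43 (SE 0.14). NR3C1 rose by 0.70 (adjusted p = 2.27e-05), and PGR fell by 0.42 (adjusted p = 0.00377) and ESR1 fell by 0.29 (SE 0.088, adjusted p = 0.0134). FKBP5 was at 44.3 FPKM against 40.9 with E2 (log2 0.11, adjusted p = 0.251), and ZBTB16 at a log2 change of 0.19 (adjusted p = 0.385).

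Against E2, 5213 genes changed with aldosterone, 3024 higher and 2189 lower, of which 156 and 97 by at least 2-fold. The share higher was 58.0%, and 51.6% with quantile normalization, but 46.6% with median-of-ratios scaling, so the direction of this majority flipped with that scaling only. All 30 proliferation genes fell (30 adjusted over the list alone), led by AURKA (-1.14 ± 0.070) and CCNA2 (-1.29 ± 0.082), 15 of 19 cholesterol and fatty acid synthesis genes fell (16 adjusted over the list alone), led by SCD (-1.15 ± 0.073), and 10 of 15 stress response genes rose and 1 fell (10 and 1 adjusted over the list alone), led by DDIT3 and TRIB3 (1.78 ± 0.076). Each of these lists passed at the preset correlation and had adjusted p = 0.0603 with an estimated correlation. Of 13 NF-kB and inflammatory genes 12 rose (12 adjusted over the list alone), led by TNFAIP3 (1.88 ± 0.12), with adjusted p = 0.0789 with an estimated correlation. Steroid metabolism genes (7 of 13 higher, 4 lower) included CYP1A1 (2.41 ± 0.14) and AKR1C3 (2.46 ± 0.10), with adjusted p = 0.119 with an estimated correlation. Shared NR3C response genes (12 of 19 higher, 1 lower) had adjusted p = 0.131 with an estimated correlation. Cell cycle arrest genes (7 of 12 higher, 1 lower) included CDKN1A (1.71 ± 0.080) and GADD45A (1.85 ± 0.096), with adjusted p = 0.153 with an estimated correlation. For all 3 lists the numbers were the same adjusted over the list alone.

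Estradiol-induced genes (19 of 28 lower, 3 higher, the same adjusted over the list alone) and estradiol-repressed genes (5 of 9 higher, 6 adjusted over the list alone) each had adjusted p = 0.141 with an estimated correlation under aldosterone, and luminal genes (5 of 14 lower and 2 higher, 6 and 2 adjusted over the list alone) had adjusted p = 0.478 with an estimated correlation. The mineralocorticoid response list did not pass (6 of 15 higher, 1 lower, adjusted p = 0.277), and within it TSC22D3 rose by 0.56 ± 0.071 while SGK1 was at 0.05 (adjusted p = 0.645). Progestin-induced, androgen-induced, interferon-stimulated, basal, receptor, hypoxia and stromal lists did not pass either (adjusted p = 0.621, 0.633, 0.57, 0.215, 0.283, 0.942 and 0.415), and for hypoxia the median was below 0 while the test pointed up. With an estimated correlation, the lists past the threshold fell from 10 to 0 for aldosterone.

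DHT added to E2 raised C1orf116, known as specifically androgen-regulated gene, from 0.295 ± 0.0454 to 9.49 ± 0.126 FPKM (log2 3.02 ± 0.080, adjusted p = 1.32e-13). AQP3 rose by 2.57 ± 0.079, SEC14L2 by 2.16 ± 0.10, the tight junction gene CLDN8 by 1.76 ± 0.11 and the metalloreductase gene STEAP1 by 1.49 ± 0.062, with reads that its paralogs may share. TFF1 fell by 1.18 (SE 0.13) and CXCL12 fell by 0.80 (SE 0.087). ESR1 and PGR did not pass (log2 0.05 and -0.13).

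Against E2, 310 genes changed with DHT, 227 higher and 83 lower, of which 18 and 2 by at least 2-fold. This number was 696 without E2 replicate 3, 212 to 282 without each of the other libraries, and 191 when only these 2 groups were fitted. Of 15 androgen-induced genes 8 rose (10 adjusted over the list alone), among them SEC14L2, AZGP1 (1.72 ± 0.13), FKBP5 (0.89 ± 0.076) and PIP (0.71 ± 0.086), with adjusted p = 0.00419 with an estimated correlation. Shared NR3C response genes (6 of 19 higher and 1 lower, 12 and 1 adjusted over the list alone, with SGK1 at 0.95 ± 0.083 and ZBTB16 at 1.27 ± 0.17), mineralocorticoid response genes (7 of 15 higher, and 10 higher and 1 lower adjusted over the list alone) and steroid metabolism genes (4 of 13 higher, 5 adjusted over the list alone) each had adjusted p = 0.0347 with an estimated correlation. Of 30 proliferation genes none passed, also adjusted over the list alone, and 9 had an unadjusted p under 0.05. The median of that list was -0.14, and its adjusted p = 8.15e-07 at the preset correlation became adjusted p = 0.362 with an estimated correlation. Estradiol-induced genes (4 of 28 lower and 3 higher, 8 and 4 adjusted over the list alone) also had adjusted p = 0.362 with an estimated correlation. Progestin-induced genes (6 of 16 higher, 8 adjusted over the list alone), stress response genes (1 of 15 higher, 5 adjusted over the list alone), NF-kB genes (1 of 13 higher, TNFAIP3, also adjusted over the list alone) and interferon-stimulated genes (none of 16, also adjusted over the list alone, and 0 with unadjusted p under 0.05) had adjusted p = 0.185, 0.231, 0.484 and 0.604 with an estimated correlation. The other 8 lists did not pass, with the smallest adjusted p = 0.117 for cholesterol synthesis, and for luminal genes the median was above 0 while mean and test pointed down.

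**Figure D3:**
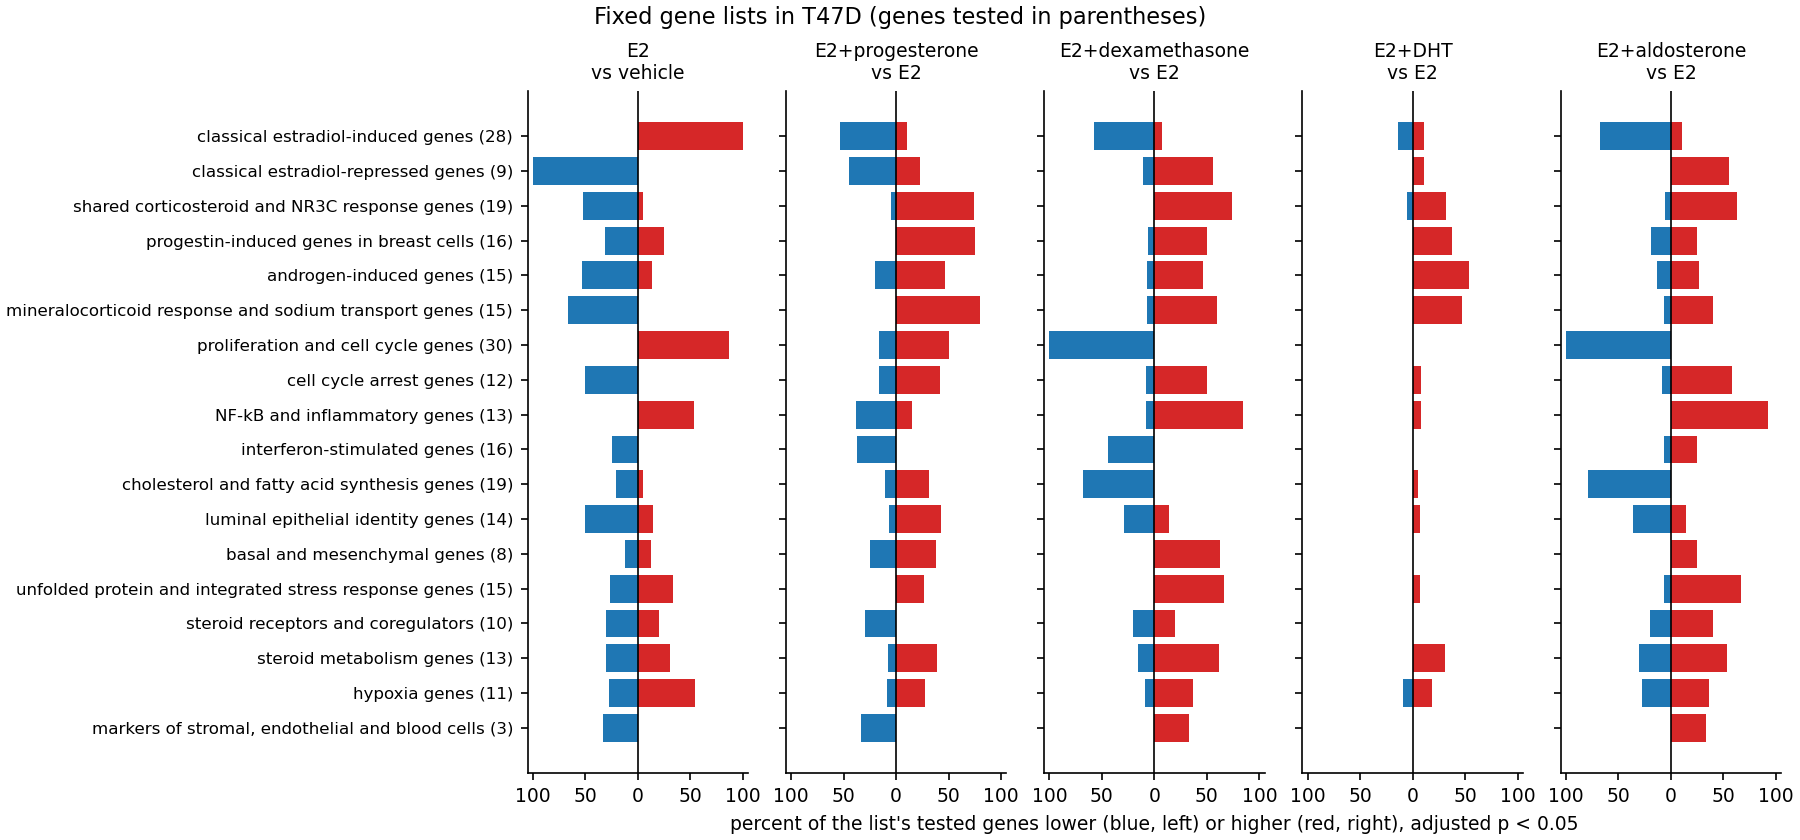
Share of each of the 18 gene lists that changed in T47D. For each list and comparison the bar length gives the percent of tested members that were lower (blue, left) or higher (red, right) past the adjusted p threshold, with 3 libraries per group. All 30 proliferation genes were lower with dexamethasone and with aldosterone, against 0 with DHT.

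Dexamethasone, a synthetic steroid that carries a fluorine atom, and aldosterone, a natural steroid with an aldehyde group, were compared at the same dose and time. They differed in 42 genes, 28 higher with dexamethasone and 14 lower, of which 2 and 0 by at least 2-fold. KRT4, a keratin, was higher with dexamethasone by 1.16 ± 0.076 (5.12 ± 0.0159 against 1.75 ± 0.149 FPKM, adjusted p = 3.79e-07), as were AZGP1 by 1.01 ± 0.13 (adjusted p = 0.000836) and TRNP1 by 0.96 ± 0.097. FKBP5, a co-chaperone that glucocorticoids induce, was also higher with dexamethasone, by 0.52 (95% interval 0.36 to 0.68, adjusted p = 0.0027). TFF1 was higher with aldosterone (-0.99, 95% interval -1.27 to -0.71, adjusted p = 0.00133).

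For the genes that follow, the test of the difference between the 2 steroids did not pass. The difference was -0.22 for GDF15 (95% interval -0.48 to 0.04), -0.30 for DDIT3 (-0.51 to -0.09, adjusted p = 0.385), 0.10 for CCNA2 (-0.08 to 0.27), -0.03 for INSIG1 (-0.26 to 0.21) and 0.07 for SGK1 (-0.11 to 0.24). Against E2, 4022 genes changed the same way with both and 5 in opposite ways, and 62.2% of the 4022 changed more with aldosterone, with a slope of 1.03. Both comparisons share the E2 libraries, which alone gave a simulated correlation of 0.499 against 0.937 observed and a covariance of 0.00711 against 0.123. Part of the overlap may come from this: 2215 genes rose with both against 630 if the comparisons were independent, and 1807 fell against 375. The number of genes that differ was 10 when only these 2 groups were fitted and 21 to 29 without each library in turn.

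The other ligands were further apart at the same dose and time. Progesterone and dexamethasone differed in 5980 genes (2301 higher with progesterone), progesterone and aldosterone in 6412 (2388 higher), progesterone and DHT in 2988 (1139 higher), dexamethasone and DHT in 3483 (1753 higher), and DHT and aldosterone in 4021 (1863 higher). With median-of-ratios scaling the share higher with progesterone moved from 38.5% to 51.9% against dexamethasone, from 37.2% to 52.2% against aldosterone and from 38.1% to 54.2% against DHT, but was 44.2, 44.2 and 45.1% with quantile normalization, so these directions flipped with the first scaling only. Those of DHT against aldosterone (46.3% higher with DHT, to 54.7 and 50.4%) and of dexamethasone against DHT (50.3% higher with dexamethasone, to 46.1 and 49.8%) flipped with both. Dexamethasone against DHT also flipped without each library in turn (47 to 49.8%). RBP2 was higher with progesterone than with dexamethasone by 5.49 ± 0.47, and GDF15 was lower by 3.55 (SE 0.12). S100P was higher with progesterone than with DHT, an androgen that lacks the acetyl side chain of progesterone, by 3.74 ± 0.16, and C1orf116 was lower by 2.49 (SE 0.080). CHRM4 was higher with progesterone than with aldosterone by 2.98 ± 0.089. GDF15 was higher with dexamethasone than with DHT by 2.83 ± 0.12 and, with DHT set beside aldosterone, was lower by 3.05 (SE 0.12). All 30 proliferation genes were higher with DHT than with aldosterone, with adjusted p = 0.0522 with an estimated correlation.

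**Figure D4:**
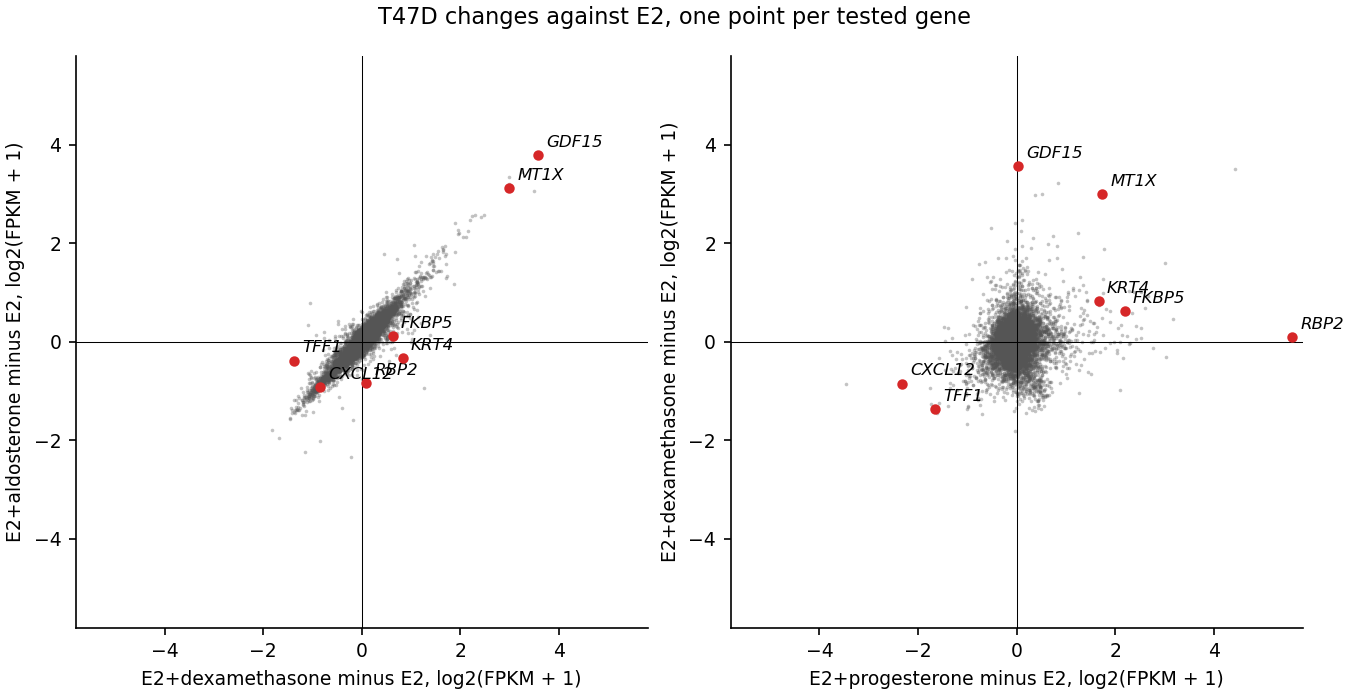
Changes against E2 compared between ligands in T47D. Each point is 1 of 12113 genes, with the log2 change for dexamethasone or progesterone on 1 axis and for aldosterone or dexamethasone on the other. Labelled red points are named genes, and all values are means of 3 libraries per group with the same E2 libraries in both axes. The correlation was 0.937 for aldosterone with dexamethasone and 0.157 for dexamethasone with progesterone.

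In the overlap of all other ligand pairs, the shared E2 libraries alone gave correlations of 0.496 to 0.5. Progesterone and DHT raised 146 genes in common against 22.3 if independent (r = 0.386, covariance 0.0218 against 0.00706 simulated), and dexamethasone and DHT 122 against 47.3 (r = 0.471, covariance 0.0302 against 0.00709). Progesterone and dexamethasone raised 361 in common against 248 (r = 0.157, covariance 0.0171 against 0.00707), progesterone and aldosterone 332 against 297 (r = 0.096, covariance 0.0111 against 0.00703), and DHT and aldosterone 92 against 56.7 (r = 0.455, covariance 0.0307 against 0.00703). Genes lower in common were 442 against 242 for progesterone and dexamethasone and 427 against 255 for progesterone and aldosterone. Part of each excess may come from the shared libraries. Genes that rose with progesterone and fell with dexamethasone were 316 against 204 if independent, and those that fell with progesterone and rose with dexamethasone 219 against 294. With aldosterone in place of dexamethasone these were 344 against 215 and 284 against 353. AQP3 and FKBP5 rose with both progesterone and DHT, and TFF1 and CXCL12 fell with both.

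In MCF7, the authors' deposited table for E2 held 2119 genes past the threshold, 1260 higher and 859 lower. GREB1, an ER-induced cofactor, was higher by 3.02 ± 0.12, EGR3 by 3.12 ± 0.21, PGR by 2.73 ± 0.17 and CXCL12 by 2.68 ± 0.19 in the authors' deposited table, and DAB2 was at -2.81 ± 0.24. All 30 proliferation genes were higher in the authors' deposited table for E2, as in those for E2+Prog, E2+Dex, E2+DHT and E2+Aldo. Of 30 estradiol-induced genes 23 were higher in the authors' deposited E2 table and 24 in that for E2+Dex. The authors' deposited table for dexamethasone alone held 518 genes, 280 higher, with FKBP5 at 2.91 ± 0.13, SGK1 at 2.61 ± 0.18, PSCA at 2.34 ± 0.13 and DAB2 at -1.80 ± 0.18, and 12 of 22 shared NR3C response genes were higher in it.

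Few genes passed in the authors' deposited tables for the other ligands alone: CYP1B1 for progesterone (0.35 ± 0.075, with 103 genes at an unadjusted p under 0.05), CRAT, PKIB, MUC5B and LRP1 for DHT, and 22 for aldosterone, 8 of them higher. For DHT 254 and for aldosterone 491 of 18354 genes had an unadjusted p under 0.05. In all 3 tables this share lay under 0.05, the share met without any effect, so the authors' tests appear conservative. Only 5900 genes had an adjusted p for aldosterone. Few passing genes thus do not show that these ligands had no effect. Tables the authors deposited for E2 with a ligand held 1627 genes for E2+Prog, 2468 for E2+Dex, 2250 for E2+DHT and 3192 for E2+Aldo. TFF1 was higher in the authors' deposited E2 and E2+Dex tables and lower in that for dexamethasone alone (-1.16 ± 0.097). KRT13 led the authors' deposited E2+Dex table (3.40 ± 0.25). Of the genes higher in the authors' deposited E2 table, 962 were also higher with E2+Dex (76.5%, 138 if independent) and 1114 with E2+Aldo (88.5%, 176 if independent). Part of these overlaps may come from shared comparison libraries, whose identity the files do not give.

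The 240 genes higher by a log2 fold of at least 1 in the authors' deposited MCF7 table for E2 were then tested in T47D, where 196 of them passed the filter. P-values of the MCF7 lists were not adjusted over lists or comparisons, unlike those of the fixed gene lists. With E2, 154 of them rose and 4 fell in T47D (p = 0.0288 with an estimated correlation). Dexamethasone lowered 134 and raised 14, among them TFF1 (lower), and aldosterone lowered 135 and raised 13, with medians of -0.51 and -0.54 and p = 0.0202 and 0.0173 with an estimated correlation. Progesterone lowered 49 and raised 43 with a median of -0.04, while the test pointed up and did not pass (limma camera, p = 0.825 at the preset correlation). DHT raised 12 and lowered 7 while the median of -0.07 and the test pointed down, with p = 0.00022 at the preset correlation and p = 0.366 with an estimated correlation. How many of the 196 genes were proliferation genes was not counted. All 30 proliferation genes were higher in the authors' deposited E2 table (median log2 0.987), and all fell in T47D with dexamethasone and with aldosterone. Of 87 tested genes lower with E2 in MCF7, E2 lowered 70 in T47D and raised 5 (p = 0.000953 with an estimated correlation). Higher and lower numbers for that list were 29 and 22 with progesterone, 33 and 14 with dexamethasone, 8 and 1 with DHT and 36 and 13 with aldosterone, with p = 0.392, 0.375, 0.314 and 0.469 with an estimated correlation. Across 11583 genes, log2 values of the authors' deposited MCF7 table and the T47D change correlated with r = 0.516 (rho 0.518) for E2. For the E2+ligand tables beside E2+ligand against vehicle in T47D, r was 0.499 for progesterone, 0.204 for dexamethasone, 0.476 for DHT and 0.163 for aldosterone.

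ER binding in MCF7 after 45 min was read with antibody lot L1911 in 4 lists, with 495 peaks for vehicle, 7020 for E2, 528 for R5020 (a synthetic progestin) and 3534 for E2+R5020. Of the E2 peaks, 47.6% (95% interval 46.4 to 48.8) were also called with E2+R5020, against 0.15% after circular shifts, and 95.3% of the E2+R5020 peaks were E2 peaks. When E2 peaks were divided by score into 4 bins of equal size, 96.9% of the strongest bin and 9.57% of the weakest were kept, and with equal numbers of the strongest peaks 78.5% were kept. The E2 peak with the highest score, on chromosome 2 from 11638580 to 11639116 (score 399.8), was in all 4 lists and ranked 3 with E2+R5020 and 15 with vehicle. R5020 peaks lay in the vehicle list for 78.2% (95% interval 74.5 to 81.5). The lists have no replicates, so their intervals cover only the number of peaks.

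After 4 h with the same lot, there were 27795 peaks for vehicle, 64244 for E2, and 47083, 66545, 23435 and 30622 for the libraries titled E2+Dex, E2+DHT, E2+Aldo and E2+Prog, whose treatment fields name other ligands. Of the E2 peaks, 83.3% (95% interval 83.0 to 83.6) were kept in the library titled E2+DHT, 64.3% (63.9 to 64.6) in E2+Dex, 45.3% (44.9 to 45.6) in E2+Prog and 34.8% (34.5 to 35.2) in E2+Aldo, against 37.8% in vehicle. Shifted lists shared 0.594 to 1.72%. In the strongest of the 4 score bins, 100% (E2+DHT), 99.7% (E2+Dex), 97.2% (E2+Prog) and 91.7% (E2+Aldo) were kept, and in the weakest 53.9, 24.4, 7.05 and 2.50%. A peak on chromosome 2 from 11670818 to 11671667, with the highest E2 score of 669.4 (tied with another), was in every 4 h list and ranked 1 to 4 in the 4 lists titled with a ligand. All 4 of these lists held 20252 of the E2 peaks (31.5%), and 9354 (14.6%) were in none. Of the library titled E2+DHT 19.0% of peaks lay outside both the E2 list and the vehicle list, against 10.1, 2.78 and 1.11% for those titled E2+Dex, E2+Prog and E2+Aldo. When equal numbers of the strongest peaks were compared, 23435 to 64244 depending on the list, 78.7 to 82.1% were kept with every ligand and 68.8% in vehicle.

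**Figure D5:**
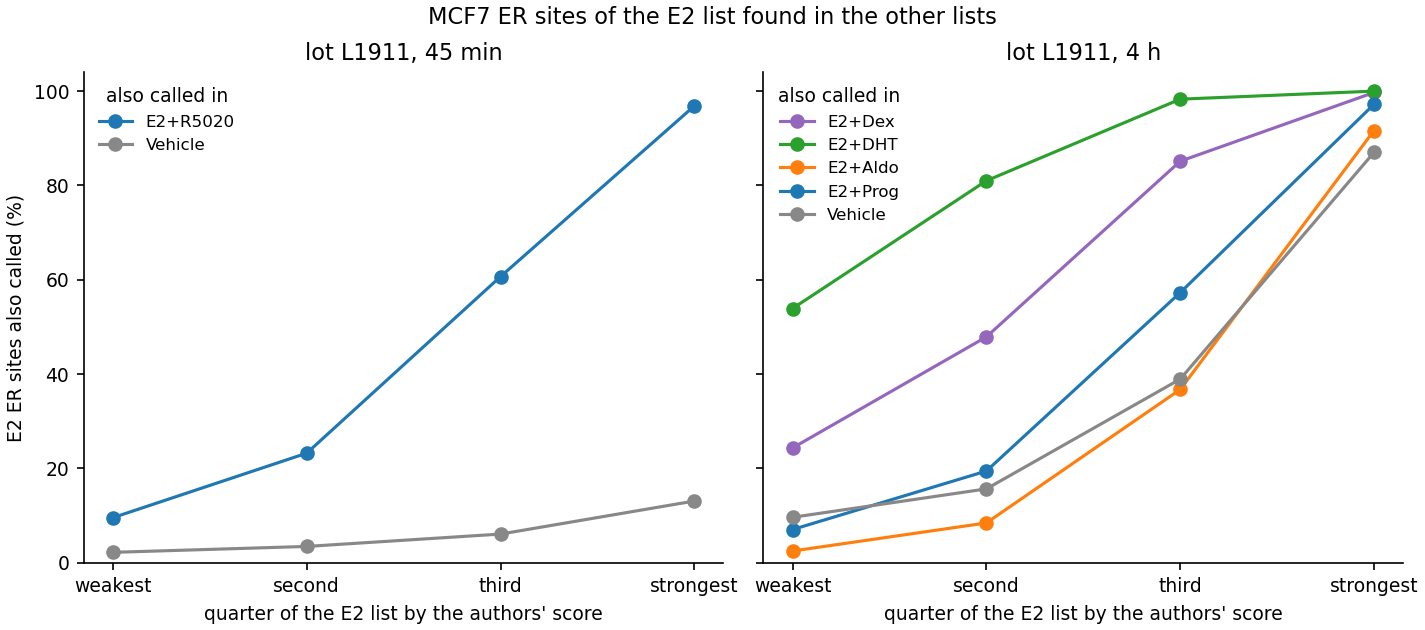
Share of E2 peaks kept with an added ligand, by score, in MCF7 with antibody lot L1911. Points joined by lines show the percent of E2 peaks overlapped by a peak in the list titled with the ligand or in the vehicle list. The 4 bins of equal size run from the weakest to the strongest score, at 45 min and 4 h, with 1 list per condition. The strongest bin was kept at 91.7% or more in every list with E2 and a ligand. In vehicle it was kept at 13.1% (45 min) and 87.0% (4 h). The weakest bin was kept at 2.50% with E2+Aldo and 53.9% with E2+DHT.

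With antibody lot F0515, E2 at 45 min gave 115299 and 27294 peaks in its 2 replicate lists, and 29.7% of the first were in the second and 59.8% of the second in the first. E2+DHT (81535 peaks) kept 40.6% of the first E2 list and 59.8% of the second, and E2+Aldo (60185 peaks) kept 24.3% and 58.0%. With an overlap of 50 percent of both peaks required, these shares were 21.7 and 9.39% for E2+DHT and 11.3 and 2.72% for E2+Aldo. At an overlap of 1 bp, the 2 vehicle lists at 45 min, which lack E2, held 23.8 and 12.5% of the first E2 list. They held 38.5 and 23.8% of the second E2 list. At 75 min, E2 gave 80661 peaks and E2+Dex, with E2 given 15 min before dexamethasone, 57036, which kept 41.9% (95% interval 41.5 to 42.2) of all E2 peaks and 93.0% of the strongest score bin. At a stricter score 16.8% were kept, and the lowest scores of the 2 lists were 224.3 and 50.1. The vehicle list at 60 min, which lacks E2, held 44.6% of all E2 peaks at 75 min, more than E2+Dex did. That vehicle list covered 103.27 Mb against 20.449 Mb for E2+Dex, and after circular shifts they held 7.131 and 1.959% of the E2 peaks. The 2 shares are thus not on equal terms. Ligands without E2 gave 86052 peaks for DHT and 161900 for aldosterone at 45 min, and 56857 for dexamethasone at 60 min, while vehicle gave 49361 and 29905 at 45 min and 92714 at 60 min. The reference set was the 6738 sites called with E2 at both times with lot L1911. Of these, the F0515 lists for E2 held 39.0 and 58.1% at 45 min and 96.1% at 75 min, E2+Dex at 75 min 92.7%, and vehicle 12.4 and 6.09% at 45 min and 51.3% at 60 min.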

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

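Pseudocount 0.1, median-of-ratios scaling, quantile normalization, leaving out libraries in the tests of MCF7 lists, the difference of MCF7 tables and bins of peaks were chosen after the results had been seen. No named gene or list that passed turned its direction under these alternatives. The majority of changed genes did turn with median-of-ratios scaling, from 45.7 to 56.6% higher with progesterone, 54.9 to 46.9% with dexamethasone and 58.0 to 46.6% with aldosterone, and in every comparison between ligands except dexamethasone and aldosterone. With quantile normalization it turned only between DHT and aldosterone and between dexamethasone and DHT. With progesterone it also turned without E2 replicate 3 (51.4%) and without E2+Progesterone replicate 1 (50.4%). Between dexamethasone and DHT it also turned with a pseudocount of 0.1 (49.7%) and without each library in turn (47 to 49.8%). Of the numbers of genes changed in T47D, 141 of 149 alternative values stayed within 1.5 times the reported one and 8 moved. For single named genes, 5386 of 5556 values kept their call, 150 lost it and 20 gained it, most often for POC1B-GALNT4 between dexamethasone and aldosterone (10 alternatives) and TNFAIP3 with DHT (9). ZBTB16 lost its call between dexamethasone and aldosterone in 7, CD68 and CDH3 theirs with E2 in 5 and 4, PGR with progesterone in 4, and TFF1 between dexamethasone and aldosterone in 1, with only the 2 groups fitted. For single lists, 740 of 810 kept their call, 69 lost it and 1 gained it. A blocking term for replicate number gave 5919 genes for E2 against vehicle, 3047, 5166, 423 and 5744 for added progesterone, dexamethasone, DHT and aldosterone, and 49 between dexamethasone and aldosterone, and moved no number by over 1.5 times. The numbers were not taken to pair the libraries, since the labels do not say so. The data hint at a pairing in part. Residual correlations were above 0.1 in 21 of 45 same-number pairs, and same-number pairs averaged 0.109 against -0.0549 for other numbers. In addition, 12 of 18 libraries were closest to their own number, and all 3 pairs of the E2 and dexamethasone groups were above 0.1. The count tests and count scaling planned for T47D were not run because the file holds FPKM, and peaks near E2-induced genes were not run because gene positions were not used here. Depth limits genes of low level: 7998 were not tested, and a change at or below 1 FPKM is compressed on the scale used.

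With only the 2 compared groups fitted, 191 genes changed with DHT and 10 differed between dexamethasone and aldosterone, with fewer libraries to estimate the spread. With an estimated correlation, the lists past the threshold were 2 for E2 (from 10), 4 for progesterone (from 12), 5 for dexamethasone (from 13), 4 for DHT (from 10) and 0 for aldosterone (from 10). With an estimated correlation the test of MCF7 E2-higher genes gave p = 0.366 with DHT, and that of E2-lower genes 0.392 with progesterone, 0.375 with dexamethasone and 0.314 with DHT. With MCF7 lists at an adjusted p of 0.01 and any fold, and the preset correlation, E2-higher genes gave p = 0.0142 and E2-lower genes p = 0.36 with progesterone, and E2-lower genes p = 0.00176 with aldosterone. For all other changes the cause was not tested.

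Leaving out each library in turn, genes changed with DHT ran from 212 to 696, the highest without E2 replicate 3, and those between dexamethasone and aldosterone from 21 to 29. Lists past the threshold with DHT ran from 6 to 11, and p for the E2-lower MCF7 genes with aldosterone from 0.0352 to 0.0992. Genes changed ran from 4559 to 5578 with E2, 1949 to 2518 with progesterone, 3653 to 5212 with dexamethasone and 4127 to 5713 with aldosterone. ESR1 lost its call with aldosterone without E2 replicate 3 or E2+Aldosterone replicate 2, and gained one with E2 without E2 replicate 3 or vehicle replicate 2, and with both scalings.

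In the authors' deposited MCF7 tables, an added absolute log2 fold of at least 1 left 382 genes for E2, 0 for Prog, 64 for Dex, 2 for DHT, 0 for Aldo, 358 for E2+Prog, 494 for E2+Dex, 394 for E2+DHT and 528 for E2+Aldo. An adjusted p of 0.01 left 0 for Prog, 10 for Aldo and 1074 for E2+Prog. Among genes in the upper 50 percent by level, MCF7 and T47D correlated with r = 0.56 for E2, 0.576 for E2+Prog, 0.533 for E2+DHT and 0.185 for E2+Aldo, and with 0.088 for E2+Prog less E2, 0.1 for E2+Dex less E2, 0.046 for E2+DHT less E2 and -0.088 for E2+Aldo less E2. Over all genes the last 4 were 0.071, 0.109, 0.078 and -0.093.

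At a stricter score, the F0515 lists at 45 min held 22270 and 15763 peaks for vehicle, 73914 and 17435 for E2, 41323 for DHT, 38433 for E2+DHT, 69289 for Aldo and 27331 for E2+Aldo. The later ones held 49889 for vehicle and 24882 for Dex at 60 min and 11582 for E2+Dex at 75 min. The L1911 lists at 45 min held 260 for vehicle, 3498 for E2, 273 for R5020 and 1757 for E2+R5020, and at 4 h 11101 for vehicle, 32298 for E2, and 25175, 33942, 12035 and 15311 for the libraries titled E2+Dex, E2+DHT, E2+Aldo and E2+Prog.

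Of the values for shared peaks, 103 moved beyond their interval and 2 did not. The share of E2 peaks kept, in percent, is given at the stricter score, at 50 percent overlap of both peaks, and with equal numbers of peaks, in this order. With F0515 at 45 min it was 39.0, 21.7 and 48.9 (first E2 list, E2+DHT), 22.3, 11.3 and 36.8 (first E2 list, E2+Aldo), 58.4, 9.39 and 40.2 (second E2 list, E2+DHT) and 51.7, 2.72 and 39.1 (second E2 list, E2+Aldo). At 75 min it was 16.8, 29.3 and 55.5 for E2+Dex. With L1911 at 4 h it was 69.3, 56.8 and 78.7 for the library titled E2+Dex, 87.6, 76.2 and 82.1 for E2+DHT, 36.4, 24.5 and 78.9 for E2+Aldo and 46.1, 36.9 and 79.4 for E2+Prog, and at 45 min 49.1, 42.9 and 78.5 for E2+R5020.

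With 3 libraries against 3, only 10 splits exist, too few for a share under 0.05. In each comparison only the real split gave its number of genes, that is 1 of 10: 5486 against at most 1370 in another split for E2, 2602 against 0 for progesterone, 4601 against 1 for dexamethasone, 310 against 0 for DHT, 5213 against 0 for aldosterone and 42 against 0 between dexamethasone and aldosterone. Between the other ligands, the real numbers of 5980 (progesterone and dexamethasone) and 4021 (DHT and aldosterone) stood against 1, and 2988, 6412 and 3483 against 0. Lists past the threshold were 10 against 9 for E2, 12 against 10, 13 against 10, 10 against 9 and 10 against 8 for progesterone, dexamethasone, DHT and aldosterone, 1 split each, so list calls at the preset correlation carry little weight. For E2-higher MCF7 genes, 9 splits gave a p as small with progesterone (0.825, smallest other 0.122), 1 with dexamethasone (7.95e-26, other 1.64e-17), 3 with DHT (0.00022, other 2.57e-06) and 1 with aldosterone (2.47e-27, other 6.27e-20). For E2-lower genes these were 1 (0.0273, other 0.078), 1 (0.022, other 0.0341), 1 (0.00905, other 0.0257) and 2 (0.0628, other 0.0169). For any difference between the 4 ligand groups, only the real split, 1 of 100, reached the 6714 genes, with 4214 at most in another. That share is under 0.05 and is the smallest that 100 splits can give. Labels do not say whether libraries of a group came from separate cultures, so it speaks only to the spread between libraries.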

Other observations

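The tests of lists between ligands, of the MCF7 dexamethasone list and of each explanation were chosen after the results they concern had been seen. Of 16 interferon-stimulated genes, which mark antiviral signalling, 13 were lower with dexamethasone than with aldosterone in T47D adjusted over the list alone, and 1 over all genes, IFIT2 at -0.46 ± 0.091 (adjusted p = 0.0374, n = 3 libraries per group). The list had a median log2 difference of -0.44 and adjusted p = 0.091 with an estimated correlation, so it was not past the threshold.

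The 50 genes higher by a log2 fold of at least 1 in the authors' deposited MCF7 table for dexamethasone alone served as a list of corticosteroid-responsive genes in T47D, where 42 were tested. E2 lowered 24 and raised 3 (p = 0.0158 with an estimated correlation). Added to E2, progesterone raised 33 and lowered 2 (p = 0.000442), DHT raised 20 and lowered 0 (p = 0.000756), dexamethasone raised 24 and lowered 3 (p = 0.0397) and aldosterone raised 18 and lowered 5 (p = 0.313), each with an estimated correlation. The medians were 0.65, 0.31, 0.42 and 0.15 on the log2 scale. P-values of this list were not adjusted over comparisons.

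In T47D, dexamethasone and aldosterone changed 4022 genes alike. If both groups had received the same ligand, corticosteroid-responsive genes would not differ between them, but genes of the MCF7 dexamethasone list were higher with dexamethasone (6 of 42 higher and 0 lower, 18 and 0 adjusted over the list alone, p = 0.000926 with an estimated correlation), which argues against this. Activation of the glucocorticoid receptor by both ligands would raise this list with aldosterone too. It did not pass (p = 0.313 with an estimated correlation), while 62.2% of the genes changed alike changed more with aldosterone. The slope of aldosterone on dexamethasone was 0.77 in this list, against 1.03 among the genes changed alike. The list thus responded less to aldosterone than to dexamethasone, while the shared change did not. Weaker activation of the glucocorticoid receptor by aldosterone stays open. Progesterone and DHT added to E2 also raised 33 and 20 of the 42 genes, so a rise of the list does not single out that receptor. Other causes of the change common to the dexamethasone and aldosterone groups were not tested.

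The libraries titled E2+Aldo and E2+Prog had the shortest lists with a ligand at 4 h. Lower sensitivity of these lists would keep strong E2 sites and lose weak ones, and they kept 91.7 and 97.2% of the strongest of 4 score bins and 2.50 and 7.05% of the weakest. The vehicle list, which lacks E2, kept 87.0 and 9.65%, so this pattern does not tell lower sensitivity from less ER binding, and both stay open. With equal numbers of peaks, 78.9% of sites were kept for E2+Aldo. Each condition has 1 list, and titles and treatment fields name different ligands.

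With lot F0515, the 2 lists for E2 at 45 min shared few peaks. A difference in list length alone would vanish with equal numbers of peaks, but 60.1% of the first list and 34.7% of the second were shared then, which argues against length alone, and median peak widths also differed, at 164 and 935 bp. Lower ER enrichment in some lists of this lot would leave sites of the other lot out, and the first list held 39.0% of them against 96.1% for E2 at 75 min, which is consistent with it. Of the 6 lists without E2 in this lot, 3 held more than that first list (55.4% for DHT, 57.1% for dexamethasone and 51.3% for vehicle at 60 min) and 3 held less (24.7% for aldosterone and 12.4 and 6.09% for vehicle at 45 min). No biological explanation was tested.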
